A study of Mus musculus with 60 samples.

How the data were processed

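Bulk RNA-seq was done by the authors on liver from 60 male C57BL/6 mice, 1 library per mouse, in a design of 6 TCDD doses (vehicle included) by 2 chows. Tissue was collected in the first hours after lights on, at age 114 days. The labels list FastQC 0.12.1, Trimmomatic 0.39, STAR 2.7.11b and STAR 2.7.3a, and DESeq2 without a version, and name the genome builds GRCm39 and mm10 without saying what each was used for, so no coordinates are given.

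The authors deposited raw counts for each library: reads per gene from STAR, with an unstranded column and 1 column per strand. The first strand column held between 50.3% and 51.75% of the stranded reads, so the libraries were unstranded and the unstranded column was used. The authors also deposited a table of log2 values for all 60 libraries, variance-stabilised, with TCDD dose and Chow columns; it was used only to check the labels and as an alternative. In that table the dose of 59 libraries matched the labels, and 1 did not; the chow of all 60 matched. The deposited counts of each library correlated best with its own row of that table. The labels were kept throughout, and groups were never drawn from measured values.

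Gene counts per library ran from 12443934 (12.44 M) to 27856391 (27.86 M), unmapped reads from 10.29% to 29.36%, multimapping reads from 4.82% to 9.4%, and detected genes from 18868 to 22698. The 10 most abundant genes took between 16.14% and 26.04% of the counts. Of 55359 gene identifiers, 94.1% had a symbol in the reference table. Replicate pairs differed by more than counting error (chi-square per degree of freedom 10.6 to 136 over 121 pairs), and the common biological coefficient of variation was 22.6%. Whether deeper sequencing would change the calls was not tested. Multimapping reads were not counted, and values of close paralogs (Mup, Serpina1, Cyp4a12, Cyp2b, Gstm, and Fdps with its pseudogenes) are uncertain.

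Tests were run in R 4.3.3 with edgeR 4.0.16: filterByExpr by group with a minimum count of 10 (15820 genes kept), TMM factors, and quasi-likelihood F tests with robust dispersions on 12 group means from all 60 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. Standard errors are the log2 change over the square root of F, which is approximate. CPM are a gene's counts per M counts of the TMM-scaled library total, given as mean and SD of a group. The comparisons were each TCDD dose against the control of the same chow, simvastatin against plain chow at each dose and averaged over the doses, the interaction at 10 µg/kg, and the interaction over 5 doses. Fixed gene lists and cell-type marker lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Beside each list's count stands the count adjusted over the list alone; where none is printed the counts were equal. Numbers such as 0.121 with an estimated correlation are camera adjusted p-values.

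Genes to be named were set before the data were examined: for 6 comparisons, the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM in a group and, for pairs of groups, no overlap between libraries; up to 4 members of each list by adjusted p; and always Cyp1a1, Cyp1a2, Tiparp, Ahrr, Hmgcs1, Sqle and 3 others. The text names a part of these, and some of the genes that the rule names are not reported here. Genes of the smallest counts of calls were named after their values were seen.

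On simulated data with known changes the same steps recovered 35.4% of 1.5-fold and 75.5% of 3-fold changes for TCDD 10 µg/kg against vehicle, with 4 of 113 calls false. For simvastatin averaged over doses they recovered 76.8% and 100%, with 10 of 184 calls false. For the interaction at 10 µg/kg they recovered 18.2% and 68.4%, with 11 of 96 calls false. A comparison with no simulated change gave 0 calls by edgeR. The simulated genes varied independently, whereas permuting the real chow labels within each dose gave up to 68 calls for the interaction at 10 µg/kg.

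Alternatives fixed before the data were examined were RLE factors, the Wald test of DESeq2 1.42.0, no filter, a stricter filter of at least 1 CPM in at least 5 libraries, only the libraries compared, the range of the title number (below or above 100) as a covariate, an adjusted p under 0.01, a 2-fold minimum, both strand columns summed, and leaving out each library in turn. Chosen after seeing the data were library totals in place of TMM, limma on the authors' log2 values, the authors' group for the library in doubt, leaving out that library and a second one, each title-number range alone, and leaving out libraries with a strand share under 51%. Labels were also permuted in 40 splits per comparison. A response score of each library was the slope of its log2 CPM, minus the vehicle mean, on the mean of the log2 changes at 10 µg/kg on both chows, over genes called on both in the same direction; a second form took the weights from 1 chow at 3 µg/kg.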

Results

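Liver messenger RNA was sequenced from 60 male C57BL/6 mice, with 1 library per animal. From age 30 days the mice were gavaged every 4 days for 84 days, 21 gavages in all, with sesame oil (vehicle) or with the dioxin TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin), a persistent ligand of the aryl hydrocarbon receptor (AHR). The TCDD doses were 0.1, 0.3, 1, 3 and 10 µg/kg. At each dose some of the mice ate plain chow and the others ate chow that delivered about 70 mg/kg/day of simvastatin, a statin, which blocks cholesterol synthesis. The labels give 5 libraries in each of 10 groups, 6 in the group given TCDD 1 µg/kg + simvastatin and 4 in the group given TCDD 0.3 µg/kg + simvastatin. The authors' own table places the library labelled TCDD 1 µg/kg + simvastatin replicate 5 in the 0.3 µg/kg group, which would make 5 in each; the label was kept here, and the closing section gives the values of that library.

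Gene counts per library ran from 12443934 (12.44 M) to 27856391 (27.86 M), with a median of 15.55 M. Vehicle libraries averaged 16.51 ± 2.49 M and TCDD 10 µg/kg libraries 17.01 ± 2.56 M (SD, n = 5 each). With simvastatin the averages were 16.46 ± 3.21 M without TCDD and 19.8 ± 6.39 M with TCDD 10 µg/kg (SD, n = 5 each). Of 55359 annotated genes, 15820 passed the count filter and were tested. The first principal component of log2 CPM (a gene's counts per M counts of the library) held 39.2% of the variance, and the second 5.7%. All log2 values below are fold changes fitted with edgeR, followed by an approximate standard error where ± is given, and p-values are adjusted over the 15820 genes unless said otherwise.

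TCDD acts in the liver mainly by switching on AHR, whose direct targets include the cytochrome P450 genes Cyp1a1 and Cyp1a2, the feedback repressor Ahrr and the ADP-ribosyltransferase gene Tiparp. Simvastatin deprives hepatocytes of mevalonate, to which the transcription factor SREBP2 responds by raising the genes of cholesterol synthesis, the squalene epoxidase gene Sqle among them. These genes show whether each exposure reached the liver. Cyp1a1 (ENSMUSG00000032315) stood at 2.64 ± 1.54 CPM in vehicle mice (SD, n = 5) and at 71.5 ± 82.3, 1070 ± 158, 4560 ± 929, 5600 ± 380 and 6260 ± 1050 CPM at the 5 rising TCDD doses (SD, n = 5 each). On simvastatin chow it stood at 1.59 ± 0.362 CPM without TCDD and at 38 ± 40.2, 817 ± 795, 2660 ± 1150, 4470 ± 843 and 5810 ± 775 CPM at these doses (SD, n = 5 each, except 4 at 0.3 and 6 at 1 µg/kg). The 817 rests on 1 library at 2010 CPM, while the other 3 averaged 419, and the 2660 holds 1 library at 620 CPM, while the other 5 averaged 3060; the labels of both libraries are in doubt, as the closing section says. The group means were below those on plain chow at each dose, and the difference passed at none of them in edgeR (adjusted p from 0.673 to 0.998) nor averaged over the doses (-0.54, adjusted p = 0.185). Cyp1a2 (ENSMUSG00000032310) went from 1220 ± 152 to 24100 ± 3340 CPM on plain chow and from 1260 ± 87.3 to 27400 ± 6390 CPM on simvastatin chow (SD, n = 5 each). Sqle (ENSMUSG00000022351) averaged 59.8 ± 12.8 CPM in vehicle mice and 277 ± 145 CPM in mice given simvastatin alone (SD, n = 5 each).

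**Figure D1:**
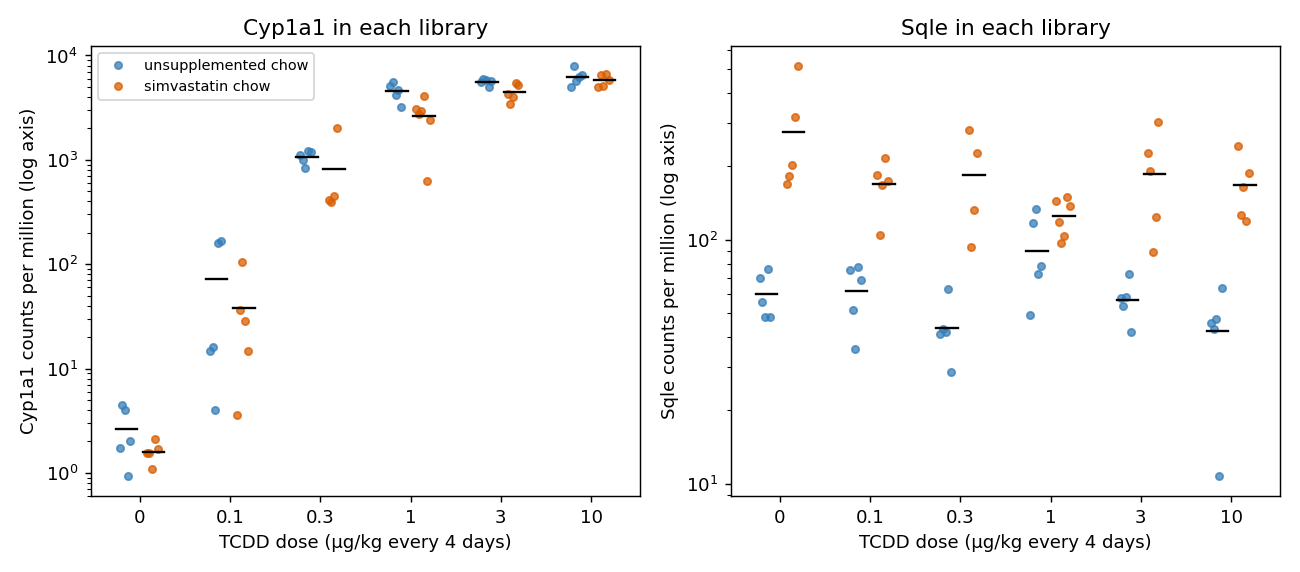
CPM of Cyp1a1 (left) and Sqle (right) in each library, on log axes, against the TCDD dose in µg/kg, with 0 for vehicle; points are libraries, blue on plain (unsupplemented) and orange on simvastatin chow, and black lines are group means. Mean Cyp1a1 rose from 2.64 to 6260 CPM on plain chow, and mean Sqle stood at 277 CPM with simvastatin alone against 59.8 CPM in vehicle mice.

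The number of genes that differed from the control of the same chow grew with the dose. On plain chow 1 gene rose at 0.1 µg/kg and 5 rose at 0.3 µg/kg, and none fell at either dose by edgeR (344 and 1170 genes at an unadjusted p under 0.05). At 1 µg/kg 232 genes rose and 96 fell, at 3 µg/kg 919 rose and 720 fell, and at 10 µg/kg 3449 rose and 2848 fell. On simvastatin chow 2 genes rose at 0.1 µg/kg and 4 at 0.3 µg/kg, with none lower by edgeR (1118 and 710 genes at an unadjusted p under 0.05). At 1 µg/kg 142 rose and 134 fell, at 3 µg/kg 694 rose and 698 fell, and at 10 µg/kg 3741 rose and 3243 fell. The 276 genes at 1 µg/kg on simvastatin chow depended on single animals, from 126 to 462 as each library was left out in turn, and with only the libraries compared edgeR called 67. A change of at least 2-fold was seen in 2077 higher and 927 lower genes at 10 µg/kg on plain chow, and in 2206 and 1207 on simvastatin chow. DESeq2 called 4 genes at 0.1 µg/kg on plain chow, and limma on the authors' log2 values called 0. With only the 10 libraries of that comparison edgeR called 0 genes (258 at an unadjusted p under 0.05).

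**Figure D2:**
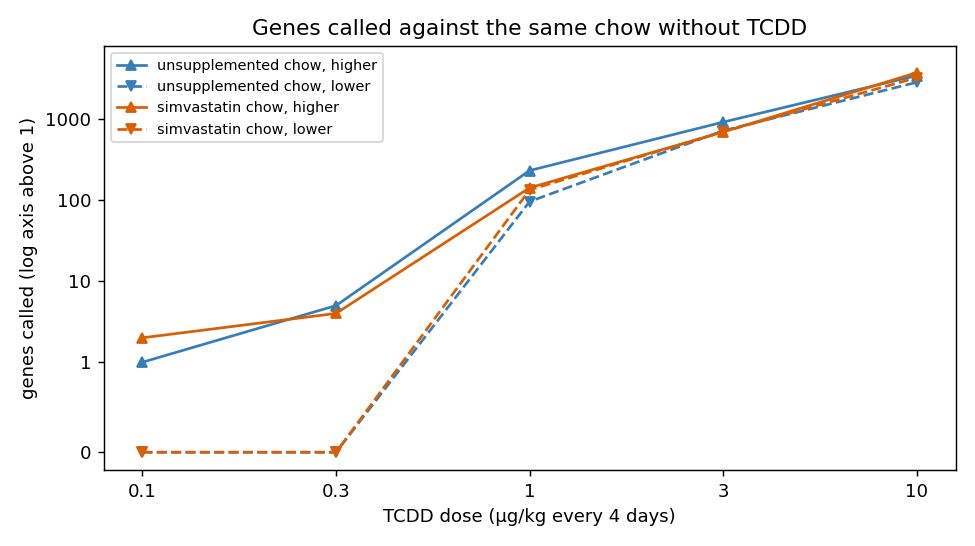
Number of genes called higher (solid lines) and lower (dashed lines) at an adjusted p under 0.05, on an axis that is logarithmic above 1, against the TCDD dose in µg/kg, each against the control of the same chow; blue is plain and orange simvastatin chow. On plain chow 1 gene was called at 0.1 µg/kg, and 3449 higher and 2848 lower genes at 10 µg/kg.

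At the lowest doses only a handful of genes passed, led by the AHR-driven P450 genes. They were named after their values were seen, since so few were called. Cyp1a1 rose at 0.1 µg/kg by 4.76 ± 0.70 on the log2 scale (adjusted p = 2.1e-04). That value averages libraries that stood apart: 3 with title numbers above 100 ran from 4.02 to 16 CPM (vehicle 1.72 to 4.5), and 2 with title numbers below 100 were at 159 and 165 CPM (vehicle 0.938 and 2). At 0.3 µg/kg Cyp1a1 rose by 8.66 ± 0.81 (adjusted p = 3.5e-10) and Cyp1a2 by 2.06 ± 0.22 (adjusted p = 7.1e-09). Htatip2, a gene of the short-chain dehydrogenase family, rose by 1.13 ± 0.16 (adjusted p = 9.4e-06). Slc46a3, which encodes a lysosomal membrane transporter, rose by 1.04 ± 0.20, and Pcp4l1, which encodes a small calmodulin-related peptide, rose by 2.50 ± 0.48 (adjusted p = 0.0116 for each). The count at 0.3 µg/kg was 3 without Vehicle replicate 1, Vehicle replicate 2 or TCDD 0.3 µg/kg replicate 5. On simvastatin chow the called genes were Cyp1a1 and the phosphate antiporter gene Slc37a1 at 0.1 µg/kg, and Cyp1a1, Cyp1a2, Slc46a3 and the actin-regulator gene Cyfip2 at 0.3 µg/kg. Neither call at 0.1 µg/kg held with only the libraries compared (0 genes by edgeR, 832 at an unadjusted p under 0.05), with limma on the authors' values (0 genes, 1481 at an unadjusted p under 0.05) or without libraries whose first strand column held under 51% of the stranded reads (1 other gene). The last of these settings dropped replicates 3, 4 and 5 of the treated group, so few libraries were left. As each library was left out in turn the count at 0.1 µg/kg ran from 1 to 30, and at 0.3 µg/kg from 2 to 5.

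At 10 µg/kg the changes reached far beyond the AHR targets named above. Several genes nearly silent in control liver were strongly expressed, and Hao1 and Hsd3b5 fell to under 1 CPM. Whether AHR drives these changes directly was not tested. The question was how broadly the highest dose changed the liver, and it is answered on plain chow first. Cyp1b1 (ENSMUSG00000024087), a P450 of the AHR battery, rose by 11.44 ± 0.92 (adjusted p = 2.1e-14) and Cyp1a1 by 11.21 ± 0.88 (adjusted p = 1.1e-14). The neuronal pentraxin gene Nptx1 rose by 10.71 ± 0.89 (adjusted p = 6.0e-14) and the collagen IX gene Col9a2 by 10.66 ± 0.57 (adjusted p = 4.4e-20). Among the exposure checks, Ahrr rose by 9.43 ± 0.66, Tiparp by 4.67 ± 0.38 and Cyp1a2 by 4.30 ± 0.25. In the other direction, the glycolate oxidase gene Hao1 (ENSMUSG00000027261) fell by 10.44 ± 0.31 on the log2 scale (adjusted p = 1.1e-33), from 295 CPM to 0.199 CPM. Hsd3b5 (ENSMUSG00000038092), a male-specific steroid dehydrogenase, fell by 10.76 ± 0.83 (adjusted p = 6.2e-15), from 210 CPM to 0.115 CPM. The organic anion transporter gene Slco1a1 fell by 5.28 ± 0.36 (adjusted p = 5.5e-17). In Cyp1b1, Cyp1a1, Nptx1, Col9a2, Hao1 and Hsd3b5 no library of one group overlapped those of the other, which the rule for naming the largest changes required.

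The balance of higher and lower genes depended on the scaling at each dose from 1 µg/kg up. With library totals in place of TMM factors the median change of all genes at 10 µg/kg was 0.32 on the log2 scale, against 0.022 with TMM, and the share of called genes that were higher was 82.5% against 54.8%. On simvastatin chow the medians were 0.252 and 0.031 and the shares 75.7% and 53.6%. At 1 and 3 µg/kg the shares that were higher were 90.3% and 81.3% with library totals against 70.7% and 56.1% with TMM on plain chow, and 75.8% and 77.4% against 51.4% and 49.9% on simvastatin chow. The changes below are relative to the TMM scaling, and no named gene reversed under library totals. List medians moved up under library totals at 10 µg/kg on plain chow, so the falls below were smaller there. Fatty acid oxidation went from -0.36 to -0.06, lipid uptake from -0.42 to -0.13, the circadian clock from -0.44 to -0.15 and acute phase from -0.48 to -0.16. Cholesterol synthesis went from -0.59 to -0.31. Only the heme, pericentral and adipocyte lists changed the sign of their median.

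Detoxification and antioxidant programs are the usual downstream reach of AHR. In the AHR gene battery 14 of 16 genes rose at 10 µg/kg (14 adjusted over the list alone), with a median change of 2.41 (camera adjusted p = 5.3e-21, and 6.8e-05 with an estimated correlation). Of the 16 genes of the NRF2 antioxidant and pentose phosphate list 10 rose (10 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 4.4e-05, but 0.121 with an estimated correlation). The quinone reductase gene Nqo1, a target of both pathways, rose by 3.59 ± 0.31 (adjusted p = 1.3e-13). Of 12 target genes of the xenobiotic receptors PXR and CAR, 4 rose and 3 fell, with a median of 0.60 and a mean of 0.26, while camera ranked them on the lower side (adjusted p = 0.631).

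Among the sterol and bile acid lists at 10 µg/kg, the fall of bile acid synthesis held with an estimated correlation and the others did not. Of 20 cholesterol synthesis genes 10 fell and none rose by edgeR (10 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 8.6e-04, but 0.388 with an estimated correlation). The lathosterol oxidase gene Sc5d fell by 1.48 and the synthase gene Hmgcs1 by 1.14 ± 0.29 (adjusted p = 0.00113), while Sqle did not pass (-0.50, adjusted p = 0.24). Of 16 genes of SREBP2 regulation and cholesterol uptake 2 rose and 9 fell, with a median of -0.46 (camera adjusted p = 0.008, but 0.199 with an estimated correlation). Of 14 bile acid synthesis genes 10 fell and 1 rose, with a median of -0.83 (camera adjusted p = 2.9e-05, and 0.0275 with an estimated correlation). Baat, which joins bile acids to taurine, fell by 1.33 ± 0.12 (adjusted p = 1.2e-13); Cyp7a1, the rate-limiting enzyme gene, did not pass (-0.43, adjusted p = 0.602). Of 16 bile acid and sterol transport genes 3 rose and 6 fell (camera adjusted p = 0.0152, but 0.134 with an estimated correlation), with the efflux pump gene Abcc4 higher by 4.57.

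Among the lists of fuel metabolism, only the fall of urea cycle and amino acid genes held with an estimated correlation, and it was about as large as that of hepatocyte markers. Of 25 fatty acid oxidation and PPARA target genes 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 1.2e-04, but 0.214 with an estimated correlation). Of 20 fatty acid and triglyceride synthesis genes 9 fell and 2 rose (camera adjusted p = 8.4e-04, but 0.227 with an estimated correlation), and the desaturase gene Fads1 fell by 2.92 ± 0.23 (adjusted p = 3.8e-15). Of 20 lipid uptake, droplet and export genes 9 fell and 4 rose (10 and 4 adjusted over the list alone; median -0.42, mean -0.07; camera adjusted p = 0.119); lipoprotein lipase (Lpl, 3.22) and the fatty acid receptor gene Cd36 (2.90) rose, and Apoa1, the main protein of high-density lipoprotein, fell by 2.01. Of 13 gluconeogenesis genes 9 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 1.1e-04, but 0.0815 with an estimated correlation). Of 16 glycolysis genes 5 rose and 6 fell (median 0.12, mean -0.03, camera adjusted p = 0.781): the muscle-type pyruvate kinase gene Pkm rose by 3.00, and the liver-type Pklr fell by 2.30. Of 11 heme metabolism genes 2 rose and 4 fell (median -0.16, mean 0.06, camera adjusted p = 0.482). Of 16 urea cycle and amino acid catabolism genes 14 fell and none rose by edgeR (14 adjusted over the list alone), with a median of -0.91 (camera adjusted p = 1.9e-09, and 0.0275 with an estimated correlation). Hepatocyte markers had a median of -0.95 in this comparison, so neither this fall nor that of bile acid synthesis (-0.83) stood out from theirs.

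Among the sex-biased, clock, acute-phase, matrix and cell-cycle lists, the fall of male-biased genes and the rise of matrix genes held with an estimated correlation. Of 15 male-biased liver genes 13 fell (15 adjusted over the list alone), with a median of -2.70 (camera adjusted p = 1.2e-10, and 0.0417 with an estimated correlation). Of 9 female-biased genes 7 rose and 1 fell, with a median of 3.63 (camera adjusted p = 0.0152, but 0.252 with an estimated correlation). Reads of the Mup, Serpina1, Cyp4a12 and Cyp2b families can be shared among paralogs, so values of single members are uncertain. Of 18 circadian clock genes 5 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0466, but 0.204 with an estimated correlation). Of 16 acute phase genes 8 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0423, but 0.562 with an estimated correlation). Of 21 extracellular matrix and fibrosis genes 20 rose (20 adjusted over the list alone), with a median of 1.84 (camera adjusted p = 8.4e-15, and 0.0275 with an estimated correlation), among them the collagen gene Col1a2 at 2.71. All 19 cell-cycle genes rose (19 adjusted over the list alone), with a median of 2.52 (camera adjusted p = 2.4e-08, but 0.121 with an estimated correlation); Ccnd1, the cyclin of the G1 phase, rose by 3.35.

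Markers of liver cell types show which populations the bulk RNA came from. Of 9 hepatocyte markers 8 fell, with a median of -0.95 (camera adjusted p = 7.7e-06, and 0.0275 with an estimated correlation). Of 10 periportal hepatocyte markers 8 fell (camera adjusted p = 1.1e-04, but 0.121 with an estimated correlation), and of 10 pericentral markers 5 rose and 3 fell (5 and 5 adjusted over the list alone; median -0.14, mean 0.08, camera adjusted p = 0.781). Of 17 macrophage and Kupffer cell markers 14 rose, with a median of 1.99 (camera adjusted p = 2.1e-06, but 0.134 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, went from 0.213 to 109 ± 77.6 CPM (n = 5 each), a change of 8.98 ± 0.84. All 7 neutrophil markers rose, with a median of 4.88 (camera adjusted p = 7.1e-04, but 0.17 with an estimated correlation), and S100a8, a calcium-binding protein of neutrophils, rose by 5.12. TCDD 10 µg/kg replicate 1 stood apart in some of these markers: its mean log2 change was 5.65 for neutrophil markers (2.29 to 3.57 in the other 4) and 2.44 for cholangiocyte markers (0.25 to 0.74 in the other 4), and it also lay apart on the first principal component. Of 8 T cell markers 5 rose and 1 fell (camera adjusted p = 0.219). Of 8 B cell markers 6 rose (camera adjusted p = 0.0171, but 0.252 with an estimated correlation). All 10 endothelial markers rose, with a median of 0.72 (camera adjusted p = 1.9e-04, but 0.184 with an estimated correlation). Of 10 stellate cell markers 5 rose (camera adjusted p = 0.0171, but 0.227 with an estimated correlation), and of 8 cholangiocyte markers 7 rose (camera adjusted p = 0.0807). Of 6 red cell markers 1 rose and 1 fell (camera adjusted p = 0.999). Of 24 markers of pancreas, fat and muscle, 6 were tested and 1 was higher. The 1 pancreas marker tested, Cela1, changed by -2.72, and the 2 muscle markers had a median of 3.83. The 3 fat markers had a median of -0.13, while their mean log2 change ran from -1.81 to -0.77 in the TCDD 10 µg/kg libraries.

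**Figure D3:**
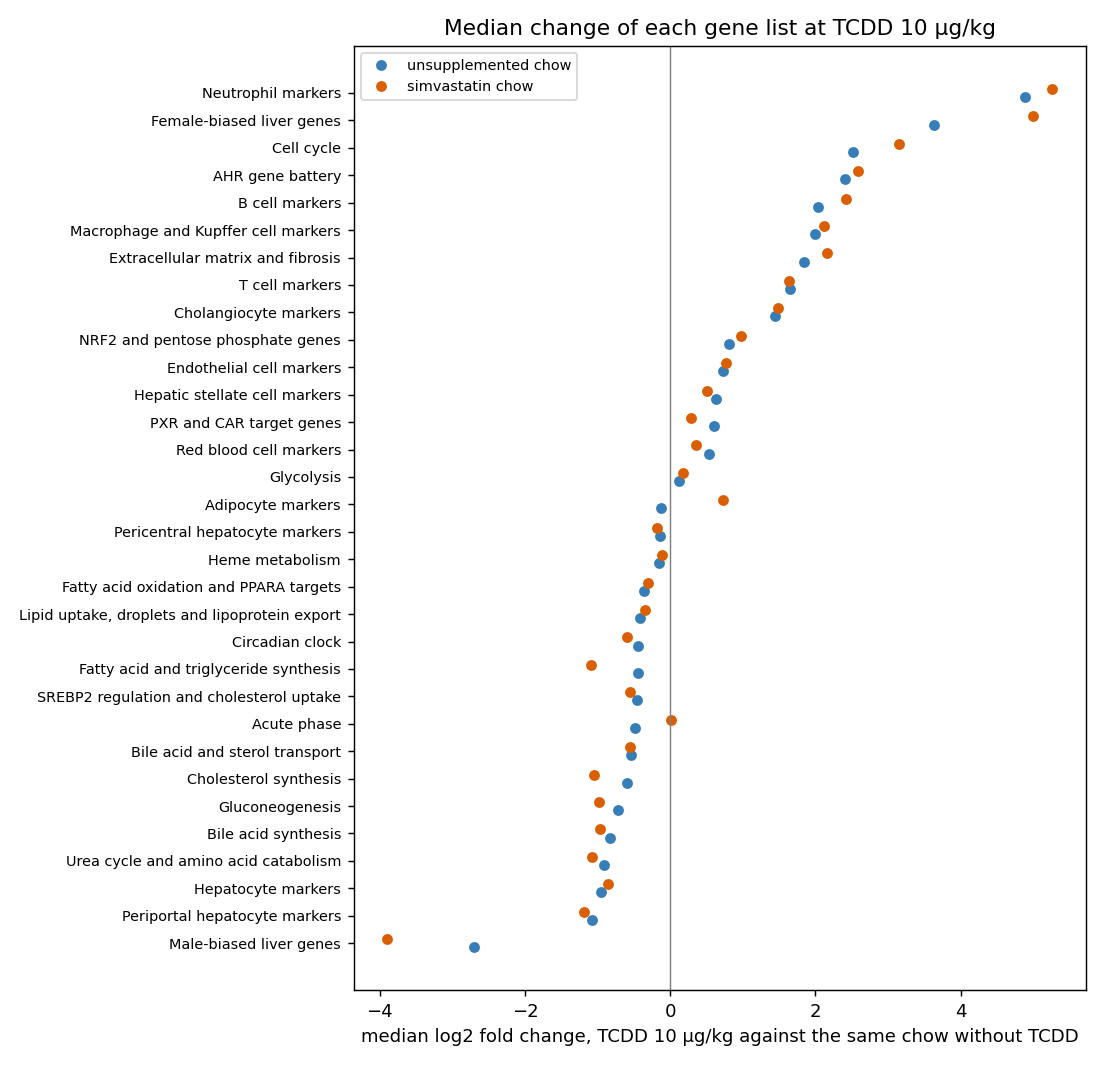
Median log2 fold change of each gene list at TCDD 10 µg/kg against the control of the same chow, with 1 line per list, blue points for plain and orange for simvastatin chow. On plain chow cell-cycle genes had a median of 2.52 and male-biased genes of -2.70, and under library totals the heme, pericentral and adipocyte medians there changed sign.

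The lower doses show which parts of this response came with less TCDD. In the AHR battery 11 of 16 genes rose at 1 µg/kg (13 adjusted over the list alone; median 1.46) and 13 at 3 µg/kg (median 2.15), with camera adjusted p-values of 6.0e-10 and 6.1e-09 with an estimated correlation. Of the NRF2 list 7 rose at 1 µg/kg (9 adjusted over the list alone) and 10 at 3 µg/kg (13 adjusted over the list alone), with 0.0311 and 0.0158 with an estimated correlation. None of the 20 cholesterol synthesis genes passed by edgeR at either dose. At 3 µg/kg 8 of 16 urea cycle and amino acid genes fell (10 adjusted over the list alone; adjusted p = 0.0735 with an estimated correlation), 6 of 19 cell-cycle genes rose (7 adjusted over the list alone; 0.343 with an estimated correlation) and 5 of 21 matrix genes rose (7 adjusted over the list alone; 0.371 with an estimated correlation). Cyp1b1 rose by 7.43 at 1 µg/kg and by 9.21 at 3 µg/kg. Hao1 fell by 0.67 at 1 µg/kg (adjusted p = 0.0383) and by 1.71 at 3 µg/kg (adjusted p = 1.1e-09). Gpnmb rose by 4.88 at 3 µg/kg (adjusted p = 1.1e-04).

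On simvastatin chow the comparison asks what TCDD did in a liver whose cholesterol synthesis genes were already raised. At 10 µg/kg AHR targets and matrix genes rose and male-biased genes fell, which held with an estimated correlation. The rise of cell-cycle genes and the fall of cholesterol synthesis genes did not (0.0854 and 0.247). Col9a2 rose by 12.41, Cyp1b1 by 11.95 and Cyp1a1 by 11.81, while Hao1 fell by 10.49 and Hsd3b5 fell by 9.66. The elongase gene Elovl3, a male-biased gene, fell by 6.06. Of 20 cholesterol synthesis genes 18 fell (19 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 2.4e-06, but 0.247 with an estimated correlation). Hmgcs1 fell by 0.75 (adjusted p = 0.0292), and Sc5d fell by 1.87. Sqle did not pass (-0.72, adjusted p = 0.0712). In the AHR battery 14 of 16 genes rose (15 adjusted over the list alone; median 2.58), with an adjusted p of 1.2e-04 with an estimated correlation. All 21 matrix genes (0.0158 with an estimated correlation) and all 19 cell-cycle genes (0.0854 with an estimated correlation) rose. All 15 male-biased genes fell (0.0248 with an estimated correlation), as did 11 of 14 bile acid synthesis genes (0.0158 with an estimated correlation) and 8 of 9 hepatocyte markers (0.0279 with an estimated correlation). Of the macrophage markers 14 of 17 rose (0.102 with an estimated correlation). At 1 µg/kg 18 of 20 cholesterol synthesis genes fell (20 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 3.9e-30, and 0.0136 with an estimated correlation). At 3 µg/kg 2 fell (9 adjusted over the list alone; 0.244 with an estimated correlation).

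The responses on the 2 chows were set side by side to see whether they were one response. At 10 µg/kg the log2 changes correlated across genes with Pearson r = 0.92 and Spearman rho = 0.86, where genes are not independent replicates. The Pearson r was 0.58 with no filter on low counts and 0.66 with DESeq2, which was also run without that filter. It was 0.77 with only the libraries of title numbers below 100, and from 0.87 to 0.94 under the other alternatives. On both chows 5170 genes were called, where 2779.9 would be if the calls on each were independent, and of these 5166 changed in the same direction and 4 in opposite directions. At 3 µg/kg 873 genes were called on both chows (144.2 if independent), all in the same direction (r = 0.74), and at 1 µg/kg 98 were (5.7 if independent), all in the same direction (r = 0.50). No library was shared between the chows.

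Simvastatin without TCDD tests the drug's own action on the liver. SREBP2 target genes are the part of the transcriptome that statins are known to raise. In all, 72 genes were higher and 1 lower than in vehicle mice, 52 and 1 of them by at least 2-fold. The count of 73 depended on the libraries used: with only the 10 compared, edgeR called 11 genes, 8 of them among the 73, and with title numbers below 100 alone 47, 42 of them among the 73. With title numbers above 100 alone edgeR called 0 (547 at an unadjusted p under 0.05). Of 20 cholesterol synthesis genes 17 rose (20 adjusted over the list alone), with a median of 1.67 (camera adjusted p = 3.9e-103, and 1.7e-06 with an estimated correlation). Idi1 (ENSMUSG00000058258), which isomerises the 5-carbon isoprenoid unit, rose by 2.84 ± 0.42 (adjusted p = 1.6e-05), the mevalonate kinase gene Mvk by 2.25 ± 0.32, Sqle by 2.21 and the lanosterol synthase gene Lss by 1.90 ± 0.25 (adjusted p = 3.5e-06). Of 16 genes of SREBP2 regulation and uptake 4 rose (8 adjusted over the list alone), with 0.00225 with an estimated correlation, and Srebf2 itself rose by 0.66 (adjusted p = 0.0358). Of 20 fatty acid and triglyceride synthesis genes 3 rose (9 adjusted over the list alone; 0.0347 with an estimated correlation), among them the acetyl-CoA carboxylase gene Acaca at 0.76 (adjusted p = 0.0019).

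The largest changes under simvastatin alone lay outside the sterol lists. Shisa4 (ENSMUSG00000041889), a membrane protein of the Shisa family, rose by 6.69 ± 0.90 (adjusted p = 4.0e-06). Scd2 (ENSMUSG00000025203), a stearoyl-CoA desaturase, rose by 4.30 ± 0.50 (adjusted p = 3.9e-07), from 6.74 to 132 ± 138 CPM (SD, n = 5). The transcription factor gene Nfe2 rose by 4.17 ± 0.57, the acetylcholine receptor gene Chrna4 by 4.12 ± 0.68 and the annexin gene Anxa13 by 3.17 ± 0.50 (adjusted p = 4.3e-05). Without Simvastatin replicate 5 the total of 73 genes was 40.

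Comparing the chows at each TCDD dose asks whether simvastatin still acted on a liver exposed to TCDD. At 0.1, 0.3, 1, 3 and 10 µg/kg simvastatin raised 4, 12, 11, 18 and 16 genes and lowered 2, 3, 25, 0 and 16. The count of 0 lower genes at 3 µg/kg is from edgeR, with 934 genes at an unadjusted p under 0.05 in either direction. These directions depended on the test. With only the libraries compared, edgeR called 6 higher and 6 lower genes at 3 µg/kg, 4 of these 12 among the 18, and 8 higher and 0 lower at 10 µg/kg (754 genes at an unadjusted p under 0.05). DESeq2 called 36 higher and 5 lower at 3 µg/kg and 32 and 46 at 10 µg/kg, and limma on the authors' values called 14 and 0, and 30 and 11. Of 20 cholesterol synthesis genes 0, 6, 0, 9 and 9 rose at these doses (18, 17, 2, 17 and 18 adjusted over the list alone), with medians of 0.85, 1.11, 0.34, 1.07 and 1.21 and camera adjusted p-values of 0.0179, 0.0077, 0.661, 0.00238 and 8.2e-04 with an estimated correlation. At 10 µg/kg Hmgcs1 (ENSMUSG00000093930) averaged 446 CPM with simvastatin and 122 CPM without, a change of 1.87 ± 0.29 (adjusted p = 8.9e-04), and Sqle 168 and 42.2 CPM, a change of 2.00 ± 0.34 (adjusted p = 0.00131). The lanosterol demethylase gene Cyp51 rose by 1.79 (adjusted p = 0.00112), Fads1 by 1.35 (adjusted p = 8.9e-04) and the lipid-droplet coat gene Plin2 by 0.88 (adjusted p = 0.00561), and the histidine ammonia-lyase gene Hal fell by 1.11. Of the 16 NRF2 genes none passed by edgeR over all genes (8 higher adjusted over the list alone; 0.0226 with an estimated correlation). Of 16 urea cycle and amino acid genes 1 fell (10 adjusted over the list alone, median -0.33, 0.025 with an estimated correlation). Medians were -0.07 in hepatocyte and -0.25 in pericentral markers, which share no gene with that list. By size this fall stood little apart from the pericentral one. Periportal markers had a median of -0.30, but they share Sds, Gls2, Hal, Ass1 and Cps1 with the urea cycle list. At 0.1 µg/kg Scd2 (3.08) and Nfe2 (3.30) rose and the clock genes Dbp (-3.26) and Per3 (-1.53) fell, but these calls are weak. With only the libraries compared, 3 of 40 splits of the libraries, the real one included, gave at least 6 genes, so chance was not excluded. Without libraries whose first strand column held under 51% of the stranded reads, edgeR called none at this dose (549 genes at an unadjusted p under 0.05). That setting dropped plain-chow replicate 5 and simvastatin-chow replicates 3, 4 and 5, so far fewer libraries were compared. Chance was not excluded at 1 µg/kg either (3 of 40 splits). These counts depended on single animals: as each library was left out in turn, they ran from 3 to 21, 3 to 32, 1 to 121, 6 to 31 and 10 to 169 at the 5 doses.

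**Figure D4:**
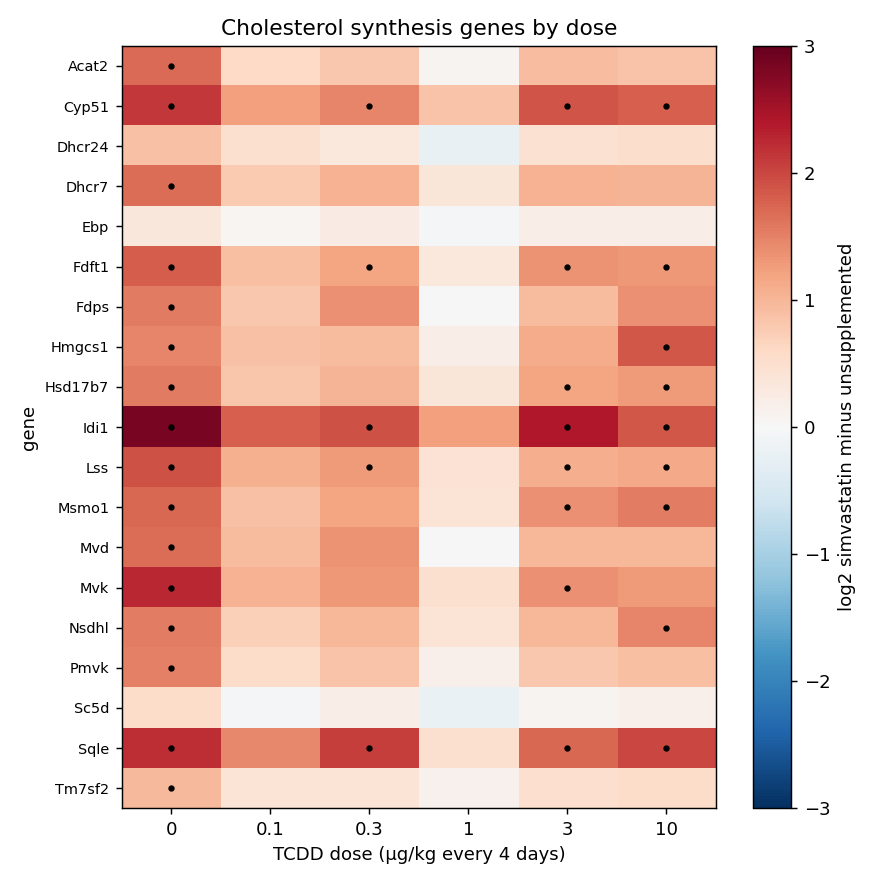
Log2 change of 19 of the 20 cholesterol synthesis genes with simvastatin against plain chow, as a color scale, with genes from top to bottom and 1 column per TCDD dose in µg/kg (0 for vehicle); dots mark an adjusted p under 0.05. The median of all 20 genes was 1.67 without TCDD, 0.34 at 1 µg/kg and 1.21 at 10 µg/kg.

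Averaging the simvastatin difference over vehicle and the 5 TCDD doses uses all 60 libraries and has the most power. It gave 512 higher and 523 lower genes, 66 and 17 of them by at least 2-fold. Of 20 cholesterol synthesis genes 19 rose (19 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 3.4e-101, and 2.2e-06 with an estimated correlation). Scd2 rose by 2.59 ± 0.19 (adjusted p = 6.0e-14), Nfe2 by 3.04 ± 0.23 (adjusted p = 6.0e-14) and Cyp51 by 1.55 ± 0.12 (adjusted p = 1.6e-13); the group mean of Scd2 was higher at 6 of 6 doses, vehicle included. The cell-cycle inhibitor gene Cdkn1a rose by 1.37 (adjusted p = 2.9e-06). Dbp (ENSMUSG00000059824), a clock-driven transcription factor, fell by 1.75 ± 0.24 (adjusted p = 3.3e-07) and was lower at 6 of 6 doses, and Per3 fell by 0.94 (adjusted p = 1.8e-07). Of 18 clock genes 4 fell and 1 rose (8 and 2 adjusted over the list alone; 0.03 with an estimated correlation). Cyp7a1, the first enzyme of bile acid synthesis, fell by 1.08, from 46.2 to 24.3 CPM (adjusted p = 0.0041). Of 12 PXR and CAR targets 5 fell (6 adjusted over the list alone; 0.03 with an estimated correlation), with Cyp2b10 lower by 1.06, though its reads may be shared with paralogs. Of 16 urea cycle and amino acid genes 9 fell (14 adjusted over the list alone; median -0.18; 0.013 with an estimated correlation), and the argininosuccinate lyase gene Asl fell by 0.42 (adjusted p = 5.0e-06). Medians were as low in hepatocyte (-0.20) and pericentral (-0.18) markers, which share no gene with that list, so this fall was not particular to urea cycle genes by size. The periportal median (-0.16) cannot serve here, since Sds, Gls2, Hal, Ass1 and Cps1 are in both lists. Of 19 cell-cycle genes 5 rose (15 adjusted over the list alone; 0.0882 with an estimated correlation). In the AHR battery 3 of 16 genes fell (4 adjusted over the list alone; 0.174 with an estimated correlation). Of 16 genes of SREBP2 regulation and uptake 7 rose and 1 fell (8 and 1 adjusted over the list alone; 0.141 with an estimated correlation). With library totals the share of called genes that were higher went from 49.5% to 64.2%.

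The interaction asks whether TCDD changed a gene differently on the 2 chows. At 10 µg/kg 5 genes passed, all with a lower change on simvastatin chow: Scd2 (-4.14 ± 0.65, adjusted p = 9.8e-04), the calcium-binding protein gene Cib3 (-4.01 ± 0.73, adjusted p = 0.00958), Shisa4 (-6.39 ± 1.25, adjusted p = 0.023), Anxa13 (-3.33 ± 0.67, adjusted p = 0.0299) and the basement-membrane gene Tinag (-4.36 ± 0.91, adjusted p = 0.0427). Scd2 rose with TCDD by 1.38 on plain chow (adjusted p = 0.0154) and fell by 2.77 on simvastatin chow (adjusted p = 1.9e-06), where simvastatin alone had already raised it. Over all 5 doses together Scd2 (adjusted p = 0.006) and Tinag (adjusted p = 0.0356) passed. None of the 20 cholesterol synthesis genes passed by edgeR (1 lower adjusted over the list alone), with a median of -0.41 (camera adjusted p = 1.9e-04, but 0.656 with an estimated correlation); 689 genes of all those tested had an unadjusted p under 0.05. The 5 calls were not stable: 2 to 5 genes passed as each library was left out in turn. With only the libraries compared edgeR called 0 genes (585 at an unadjusted p under 0.05), as it did with title numbers above 100 alone (994) and below 100 alone (761). DESeq2 called 7, all lower, and limma on the authors' values called 3, 33.3% of them higher. In 5 of 40 regroupings of the chow labels within each dose, the real one included, at least 5 genes passed, so chance was not excluded for this count. In simulated data with the fitted spread of each gene, 18.2% of genes given a 1.5-fold interaction and 68.4% of those given a 3-fold one were recovered. There the genes varied independently and no other TCDD response was present, so the shares may differ in the real data.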

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

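The tests of explanations below were all chosen after the result was seen; the search for libraries far from their group and the interaction tests were set before the data were examined. In 14 of 108 groups of libraries, counted over check genes and quality measures, 1 library lay far from the others by Dixon's criterion; chance alone gives about 1 in 20.

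Among the AHR target genes, Cyp1a1 was at 2010 CPM in TCDD 0.3 µg/kg + simvastatin replicate 4, where the others ran from 394 to 450, and at 620 CPM in TCDD 1 µg/kg + simvastatin replicate 5, where the others ran from 2400 to 4130. Cyp1a2 was at 8040 CPM in the former (others 3080 to 3460), and Ahrr at 0.0588 CPM in the latter (others 4.23 to 14). Tiparp was at 3.62 CPM in Vehicle replicate 5 (others 5.33 to 6.21) and at 85.5 CPM in TCDD 3 µg/kg + simvastatin replicate 5 (others 19.6 to 28.6). Among the sterol genes, Hmgcs1 was at 878 CPM in Simvastatin replicate 5 (others 691 to 740) and Sqle at 10.8 CPM in TCDD 10 µg/kg replicate 4 (others 43.3 to 63.3). The score of the TCDD response was 0.123 in TCDD 0.3 µg/kg replicate 5, against 0.033 to 0.053 in the others of its group.

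Depth and composition also stood apart in a few libraries. Gene counts were 21.56 M in TCDD 0.1 µg/kg replicate 4 (others 12.44 to 14.16), 21.94 M in TCDD 3 µg/kg + simvastatin replicate 4 (others 13.65 to 15.09) and 21.49 M in TCDD 10 µg/kg replicate 3 (others 15.35 to 16.45). The 10 most abundant genes took 21.26% of the counts in TCDD 0.3 µg/kg replicate 5 (others 16.86% to 18.04%) and 19.64% in TCDD 0.3 µg/kg + simvastatin replicate 3 (others 17.96% to 18.23%).

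The effect of TCDD at 10 µg/kg differed between the chows by an interaction test for Shisa4 (-6.39), Tinag (-4.36), Scd2 (-4.14), Cib3 (-4.01) and Anxa13 (-3.33), on the log2 scale. Over the 5 doses it differed for Scd2 (adjusted p = 0.006) and Tinag (adjusted p = 0.0356). Of 40 splits that permuted the chow within each dose, the real one included, 5 gave at least 5 genes at 10 µg/kg (highest other 68) and 7 gave at least 2 genes over the doses (highest other 113), so chance could not be excluded for either count.

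The first pattern weighed is the pair of libraries out of place on simvastatin chow. The score of TCDD 1 µg/kg + simvastatin replicate 5 was 0.048, near the mean of 0.051 in the other TCDD 0.3 µg/kg + simvastatin libraries and below the range of 0.124 to 0.216 in its own group; the score of TCDD 0.3 µg/kg + simvastatin replicate 4 was 0.11, above the other libraries of its group (0.029 to 0.09). Depth is argued against as the cause, since the former held 17.91 M counts, inside the 13.7 to 18.72 M of the others. By expression, ordinary variation stays open. In log2 Cyp1a1 the libraries lay at -2.2 and 2.1 pooled SD from the others of their groups. By the score, which was tried first, they lay at -2.3 and 1.2. The pooled SD of 1.06 is carried by the TCDD 0.1 µg/kg groups, where Cyp1a1 ran from 3.59 to 165 CPM. Without them it was 0.23, and the libraries lay at -9.7 and 9.7; the SD of the others of their groups was 0.29 and 0.1. By Cyp1a1 alone such distances speak against ordinary variation, but the groups left out were chosen after the values were seen. The score over the genes called on both chows did not lie as far out. Its pooled SD of 0.05 was widened by the TCDD 10 µg/kg groups (SD 0.098 on plain and 0.077 on simvastatin chow). In the other TCDD 1 and 0.3 µg/kg + simvastatin libraries its SD was 0.035 and 0.034, so the distances by the score do not decide either. A wrong dose label for 1 or both may be the cause. The authors' table gives the former the lower dose, which goes with that for 1 of them. So does its title number, 78, since most titles run in the order of the groups. Titles 76 and 77 are labelled TCDD 0.3 µg/kg + simvastatin, 79 and 80 TCDD 1 µg/kg, and 82 TCDD 1 µg/kg + simvastatin. For the latter library, titled 77, the authors' table and the title order both go with the labelled dose.

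The second pattern is the rise of markers of other cell types at TCDD 10 µg/kg while hepatocyte markers fell. A smaller hepatocyte share alone would raise macrophage and endothelial markers alike, but macrophage markers rose more, by 1.35 on plain chow and 1.87 on simvastatin chow in mean log2 change (exact permutation p, two-sided, 0.00794 at most, the smallest that 5 against 5 can give). The libraries were not fully apart in that difference when both chows were pooled, with the smallest TCDD 10 µg/kg value at 0.56 and the highest control at 0.61. Normalization is argued against, since the hepatocyte median was -0.66 with library totals. More macrophages in the liver, or higher expression of these genes in each, may contribute to the rest, and bulk RNA gave no test between them. The difference also depends on the endothelial list. Its mean log2 change was 0.21 in TCDD 10 µg/kg replicate 1 and 0.82 to 1.1 in the others on plain chow. What that list contributes was not tested.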

How the results depend on the processing

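Chosen after seeing the data were library totals, limma on the authors' log2 values, the title-number ranges alone, the strand-share setting, the 2 settings on doubtful libraries and the splits of the libraries; the other alternatives were set before the data were examined. No paired analysis was possible because each animal has its own number and the labels pair none of them. No named gene reversed, while counts and correlations were checked only for size. The balance of higher and lower genes did tip in some settings. Averaged over doses 49.5% of called genes were higher, against 64.2% with library totals and 68.1% with title numbers below 100 alone. At TCDD 3 µg/kg on simvastatin chow 49.9% were higher, against 77.4% with library totals. With library totals the medians of the heme, pericentral and adipocyte lists changed sign at TCDD 10 µg/kg on plain chow (-0.16 to 0.15, -0.14 to 0.15 and -0.13 to 0.19), as did the heme and pericentral ones on simvastatin chow (-0.11 to 0.11 and -0.18 to 0.03). In the simvastatin and interaction comparisons some list medians within 0.08 of 0 changed sign too. With RLE factors, the stricter filter, the title-number covariate, both strand columns summed or the authors' group for TCDD 1 µg/kg + simvastatin replicate 5, no count of genes moved by over 1.5 times.

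In what follows, TCDD counts are against the control of the same chow, and simvastatin counts are against plain chow at the same dose. An adjusted p under 0.01 gave fewer genes by construction. On plain chow 3, 155 and 872 passed at TCDD 0.3, 1 and 3 µg/kg, and on simvastatin chow 2, 88 and 673. Simvastatin counts were 3, 6, 14, 8 and 15 at the 5 doses and 432 averaged, and the interactions gave 2 at 10 µg/kg and 1 over 5 doses. A 2-fold minimum, also stricter by construction, gave 163, 656 and 3004 at TCDD 1, 3 and 10 µg/kg on plain chow and 124, 563 and 3413 on simvastatin chow, 16 for simvastatin at 1 µg/kg and 83 averaged.

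For the settings of this paragraph the cause was not tested. With no filter, simvastatin chow had 2 and 162 at TCDD 0.3 and 1 µg/kg, simvastatin at 1 and 3 µg/kg had 23 and 10, and the correlation between the chows at 10 µg/kg was 0.58. DESeq2, also run without the count filter, gave 4 and 12 genes at TCDD 0.1 and 0.3 µg/kg, 26, 8 and 439 at 0.1, 0.3 and 1 µg/kg on simvastatin chow, 25, 35, 85, 41 and 78 for simvastatin at the 5 doses, and a correlation of 0.66. Library totals gave 537 genes at TCDD 1 µg/kg. On the authors' log2 values limma gave 0 at TCDD 0.1 µg/kg on plain chow (678 at an unadjusted p under 0.05; edgeR 1, DESeq2 4) and 0 on simvastatin chow (1481; edgeR 2, DESeq2 26), 2 at 0.3 µg/kg on simvastatin chow and 3 for the interaction at 10 µg/kg.

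DESeq2 and limma were not run on the compared libraries alone, so their counts in this paragraph are from all 60 libraries. With only the libraries compared, fewer libraries set the spread. By edgeR this gave 0 genes at TCDD 0.1 µg/kg (258 at an unadjusted p under 0.05; DESeq2 4, limma 0), 12 at 0.3 µg/kg, and on simvastatin chow 0 at 0.1 µg/kg (832; DESeq2 26, limma 0), 1 at 0.3 µg/kg and 67 at 1 µg/kg. Simvastatin alone gave 11, simvastatin at 0.3, 1 and 10 µg/kg gave 4, 1 and 8, and the interaction at 10 µg/kg 0 (585; DESeq2 7, limma 3).

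Settings that drop libraries leave fewer to test, and the DESeq2 and limma counts set beside them here are from all 60 libraries. Without TCDD 0.3 µg/kg + simvastatin replicate 4 and TCDD 1 µg/kg + simvastatin replicate 5, TCDD 0.3 µg/kg on simvastatin chow gave 2, simvastatin at 0.3 µg/kg 6 and the interaction over 5 doses 1. Title numbers above 100 alone gave, by edgeR, 0 for simvastatin alone (547 at an unadjusted p under 0.05; all libraries 73, DESeq2 86, limma 64), 0 for simvastatin at 10 µg/kg (1493; DESeq2 78, limma 41), 263 averaged and 0 for the interaction at 10 µg/kg (994; DESeq2 7, limma 3). Title numbers below 100 alone gave 2739 and 3205 genes at TCDD 10 µg/kg on plain and simvastatin chow, 47 for simvastatin alone, 3 for simvastatin at 10 µg/kg, 191 averaged, 0 by edgeR for the interaction at 10 µg/kg (761; DESeq2 7, limma 3) and a correlation of 0.77. Without libraries under 51% strand share, TCDD 0.3 µg/kg gave 3, TCDD 0.1 µg/kg on simvastatin chow 1, simvastatin at 0.1 µg/kg 0 by edgeR (549; DESeq2 25, limma 6), simvastatin at 0.3 µg/kg 5, 521 averaged and the interaction over 5 doses 0 by edgeR (618).

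Leaving out each library in turn gave these ranges. TCDD 1, 3 and 10 µg/kg on plain chow gave 228 to 381, 1240 to 1546 and 5532 to 6306 genes, TCDD 3 and 10 µg/kg on simvastatin chow 1012 to 1396 and 6172 to 6984, the averaged comparison 771 to 1296 and the correlation 0.9 to 0.92. TCDD 0.1 µg/kg gave 1 to 2 (2 without its replicate 2), and TCDD 0.3 µg/kg 3 to 6 (3 without Vehicle replicates 1 or 2, or its replicate 5). Simvastatin alone gave 40 to 89 (40 without Simvastatin replicate 5).

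On simvastatin chow TCDD 0.1 µg/kg gave 1 to 30: 4, 5 and 1 without Simvastatin replicates 1, 2 and 5, and 30, 8, 16 and 8 without treated replicates 1 to 4. TCDD 0.3 µg/kg gave 2 to 5: 2 without Simvastatin replicates 1, 3, 4 or 5 or treated replicate 4. TCDD 1 µg/kg gave 126 to 462: 171, 462, 126 and 165 without Simvastatin replicates 1, 2, 4 and 5, and 153 and 142 without treated replicates 3 and 4.

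Simvastatin at 0.1 µg/kg gave 3 to 21: 21, 15, 13 and 10 without simvastatin-chow replicates 1 to 4 and 3 without plain-chow replicate 4. At 0.3 µg/kg it gave 3 to 32: 3, 32 and 6 without simvastatin-chow replicates 1, 2 and 4, and 8, 7 and 9 without plain-chow replicates 1, 2 and 5. At 1 µg/kg it gave 1 to 121: 1 and 93 without plain-chow replicates 2 and 3, and 17 and 121 without simvastatin-chow replicates 3 and 4. At 3 µg/kg it gave 6 to 31: 10, 11, 10 and 9 without plain-chow replicates 1, 2, 3 and 5, and 11, 31 and 6 without simvastatin-chow replicates 1, 3 and 5. At 10 µg/kg it gave 10 to 169: 169, 19 and 12 without plain-chow replicates 1, 3 and 4, and 10, 81, 20, 78 and 17 without simvastatin-chow replicates 1 to 5.

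The interaction at 10 µg/kg gave 2 to 5: 2 without Vehicle replicates 1, 4 or 5, Simvastatin replicate 5 or TCDD 10 µg/kg + simvastatin replicates 2 or 4, and 3 without Vehicle replicate 3 or Simvastatin replicate 4. The interaction over 5 doses gave 1 to 4: 4 without TCDD 1 µg/kg + simvastatin replicate 4, and 1 without any of Vehicle replicates 1, 3, 4 and 5, Simvastatin replicate 4, TCDD 0.1 µg/kg replicates 2 and 4, TCDD 0.3 µg/kg replicates 1, 2, 4 and 5, TCDD 0.3 µg/kg + simvastatin replicates 1, 3 and 4, TCDD 10 µg/kg replicates 2 and 5, and TCDD 10 µg/kg + simvastatin replicates 1, 2, 3 and 5.

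In 40 splits per comparison, with only the libraries compared and the real split included, the real one could reach 1 in 40 at best, unadjusted over the comparisons. For simvastatin at 0.3, 3 and 10 µg/kg these fits shared 3, 4 and 6 genes with the 15, 18 and 32 calls in Results. Chance was argued against, for the counts of these fits and not for single genes, where only the real split gave as many genes. That held at TCDD 0.3, 1, 3 and 10 µg/kg on plain chow (12, 312, 1648 and 5410 genes; highest other splits 0, 2, 0 and 1), at 1, 3 and 10 µg/kg on simvastatin chow (67, 1559 and 6019; highest others 4, 1 and 0), for simvastatin alone (11; highest other 3) and at 0.3, 3 and 10 µg/kg (4, 12 and 8; highest others 2, 2 and 1), and for the average, with chow permuted within dose (1035; highest other 4). Chance was not excluded at TCDD 0.3 µg/kg on simvastatin chow (1 gene, 4 splits as many, highest other 1), or for simvastatin at 0.1 µg/kg (6, 3 and 13) and 1 µg/kg (1, 3 and 11). At TCDD 0.1 µg/kg the real count in these edgeR fits was 0 on both chows, which all 40 splits match by construction, so the splits decided nothing there (highest others 128 and 99).

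What depth limits was not tested, since no counts were thinned.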

Other observations

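The tests reported here were all chosen after the result was seen.

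A smaller TCDD response with simvastatin was looked for at 3 µg/kg and stays open. With weights from the genes that changed on plain chow, the response score on simvastatin chow differed by -0.075 from that on plain chow (exact permutation p = 0.0873, n = 5 each). With weights from simvastatin chow the difference was 0.019 (exact permutation p = 0.683), so its sign followed the chow that supplied the weights. With weights from both chows at 10 µg/kg it was -0.017 (exact permutation p = 0.476, adjusted p = 0.571 over 6 doses). Other values lean to a smaller response: across genes called on either chow, the slope of the change on simvastatin chow on that on plain chow was 0.73 at 1 µg/kg, 0.83 at 3 µg/kg and 1.02 at 10 µg/kg, though noise in the plain-chow values lowers such a slope. In libraries with title numbers above 100, Cyp1a1 at 3 µg/kg ran from 3440 to 4240 CPM with simvastatin and from 5550 to 5970 without (3 against 3), and Ahrr from 25.1 to 40.8 and from 52.9 to 63.3 CPM. In those with title numbers below 100 the ranges of Cyp1a1 lay at 5170 to 5480 and 4980 to 5680 CPM (2 against 2), and Ahrr was higher with simvastatin, at 36.6 and 44.4 CPM against 30.7 and 37.2. Tiparp ran from 19.9 to 28.6 CPM with simvastatin and from 45.8 to 54.2 without above 100, and below 100 it was at 19.6 and 85.5 against 26.1 and 17.6. Over all libraries Cyp1a1, Ahrr and Tiparp did not pass in edgeR at 3 µg/kg (-0.33, adjusted p = 0.98; -0.37, adjusted p = 0.967; and -0.11, adjusted p = 0.989), so a smaller response may exist and was not settled. At lower doses some of the libraries leaned further that way in Cyp1a1 and Cyp1a2. At 0.3 µg/kg, with TCDD 0.3 µg/kg + simvastatin replicate 4 set aside, Cyp1a1 ran from 394 to 450 CPM with simvastatin and from 836 to 1220 without, and Cyp1a2 from 3080 to 3460 and from 4210 to 6130 (3 against 5). That library was set aside for its own high Cyp1a1 and Cyp1a2 (2010 and 8040 CPM), so this gap was partly fixed by the choice. The authors' table gives it the labelled dose. At 1 µg/kg with title numbers above 100, Cyp1a1 ran from 2780 to 3070 CPM with simvastatin and from 4180 to 5610 without, and Cyp1a2 from 10200 to 11200 and from 15100 to 18000 (3 against 3). Below 100 the chows overlapped: Cyp1a1 was at 4130, 2400 and 620 CPM with simvastatin and at 4680 and 3190 without. Cyp1a2 was at 13600, 7480 and 3950 CPM against 15500 and 10600. The 620 and 3950 are from TCDD 1 µg/kg + simvastatin replicate 5. Without it the ranges still overlapped, through replicate 4 alone (4130 and 13600). Its title, 35_2, lies apart from the other titles below 100, which run from 61 to 95. The 1 library left, replicate 6 at 2400 and 7480 CPM, lay below both on plain chow, which 1 library cannot settle. Without the libraries in doubt, Cyp1a1 and Cyp1a2 did not pass over all genes at 0.3 µg/kg (-1.36 and -0.62, adjusted p = 0.867 and 0.488) or 1 µg/kg (-0.57 and -0.48, adjusted p = 0.775 and 0.277). Averaged over vehicle and the doses, without the libraries in doubt, Cyp1a2 passed (-0.25, adjusted p = 0.022; with all libraries -0.20, adjusted p = 0.167) and Cyp1a1 did not (-0.67, adjusted p = 0.0801). Since 1 of these libraries was left out for its own high Cyp1a1 and Cyp1a2, this pass is no independent support for a smaller response. The score, without these libraries, differed by -0.008 and -0.006 at 0.3 and 1 µg/kg (exact permutation p = 0.786 and 0.833), so it did not show a smaller response there.

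Several clock genes were lower on simvastatin chow, Dbp and Per3 among them. A different phase of the clock at collection, from a change in feeding time or in the hour of dissection, was the hypothesis. Across 18 clock genes, which are not independent replicates, the chow difference followed the first component of variation within groups, which held 39.9% of the variance, with an absolute Pearson r of 0.55 and Spearman rho of 0.54. This lies between the values set for and against the hypothesis (0.6 and 0.3), so a phase difference may be involved and could not be settled; the labels give no hour for each mouse.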
